A study of Mus musculus with 4 samples.

How the data were processed

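Mouse testis cells were profiled with a droplet 3' single-cell kit in 4 libraries, 1 for each of control and Znhit1 knockout at postnatal days 16 and 35. The authors deposited UMI counts per gene and barcode for the day 35 knockout library, made with Cell Ranger 7.1.0, per the file headers. The submitters' processing notes also name STAR and the genome build mm10. The deposited counts are whole numbers, not normalised. No deposited barcode had fewer than 500 UMIs. How barcodes were called as cells is not given in the sources used here. The barcode and feature lists of all 4 libraries were read, and the count matrices of the other 3 libraries were not analysed here. The lists name 32285 genes, of which 32235 matched a gene identifier of a GENCODE annotation of the same build, giving 1084 X-linked and 725 Y-linked genes.

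Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 8121 of 15306 barcodes. Of the others, 3592 barcodes had under 1000 UMIs and 4152 had over 10% mitochondrial UMIs. Scrublet, run in scanpy 1.11.5, called 235 of the 8121 cells (2.89%) doublets, and these were removed, leaving 7886. Free RNA was not subtracted. Counts were scaled per cell and log transformed, 3000 variable genes were taken, and 30 principal components and 15 neighbours gave a shared-neighbour graph. Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave 22 clusters. X-linked, Y-linked and mitochondrial genes and the genes of all lists, 2053 in all, were left out of the clustering. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, pandas 2.3.3 and matplotlib 3.10.9.

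Marker genes and gene lists, the filters, the clustering settings and the rule for named genes were fixed before the data were examined. The scoring that turned markers into names was not. A cluster took the name with the highest mean marker score, from log-scaled levels, if the score was at least 1, the lead over the next name at least 0.25 and at least 3 markers were detected at 2-fold or more. This scoring was settled after clusters had been seen, in 3 respects. Levels averaged over cells replaced summed counts, and names from summed counts are not given. The lead was dropped between consecutive germ stages, which named the first pachytene-like cluster of 371 cells. Clusters whose median UMI count was below that of all cells used divided by 3 stayed unnamed. All 4 unnamed clusters, with 989 cells (12.5%), were of this kind, but without this rule only 1 of them, of 126 cells, took a name and 863 cells stayed unnamed. The last 2 choices were also run the other way. Undifferentiated and differentiating spermatogonia were merged, as were peritubular myoid cells and pericytes. Names rest on rebuilt clusters, since no cell annotation was used here.

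Counts were summed over the cells of a class and given as CPM with exact Poisson 95% intervals. Ratios have exact conditional binomial intervals, and shares have Clopper-Pearson intervals. These cover counting error only, not variation between animals. A count of 0 was set to 3 counts in ratios. List members needed 20 UMIs over both classes. A list's median has an exact order-statistic interval over members, and its percentile is among 10000 random autosomal lists of the same size, matched on mean expression in 20 bins. With 1 library per group there was no test and no p-value.

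Genes were named by a rule. Znhit1, H2afz and H2afv were always named. In each list, and in X-linked and Y-linked genes, the rule took the 2 largest upward and the 1 largest downward ratio of at least 1.5-fold, and the member of highest CPM. Not every gene the rule took is described, and some are not reported here. Prm1, Prm2, Tnp1, Tnp2, Spaca1, Izumo1, Gapdhs, Smcp and Srcap fell outside it and were chosen after their values were seen. The same holds for the genes of the closing section other than Znhit1, Ldhc and Gm1993. The lists cover H2A.Z and its deposition machinery, the synaptonemal complex and cohesin, recombination, the DNA damage response and sex body, the piRNA pathway, pachytene transcription and metabolism, axoneme and acrosome, retrocopies of X-linked genes, histone variants, p53 targets, the cell cycle and dissociation stress.

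The ratio and list steps were tested on simulated data. Counts were drawn from Poisson distributions for 13651 genes in 2 classes with 200 genes changed. Genes were drawn independently and no single cells were simulated. The intervals assume the same distribution, so the simulation checks the computation only. It does not cover spread between cells or list members that change together. Intervals held the true ratio for 96.1% of genes, and median estimates were 0.254, 0.492, 1.97 and 3.99 for true folds of 0.25, 0.5, 2 and 4. Of 100 unchanged lists, 5 fell outside the central 95%. Alternatives were a minimum of 200 genes and 500 UMIs, at most 20% mitochondrial UMIs, doublets kept, resolution 2, 2000 variable genes, equal weight for each cell, and list minimums of 5 and 100 UMIs.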

Results

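Single-cell RNA sequencing was carried out on mouse testis with a droplet 3' kit, to examine what loss of ZNHIT1 does. ZNHIT1 is a subunit of the SRCAP complex, which places the histone variant H2A.Z into chromatin. The labels gave 4 groups of 1 library each, control and Znhit1 knockout at postnatal days 16 and 35. The control library of day 16 listed 14381 cell barcodes and the knockout library of that day 13789. The control library of day 35 listed 13734 and the knockout library of that day 15306. Between 45 and 81 barcode sequences were shared by any pair of libraries. Counts were analysed for the day 35 knockout library, and the count matrices of the other 3 libraries were not analysed here. No value below therefore compares genotypes or ages, and no test was made. Each value describes cells of 1 library, and its 95% interval covers counting error only.

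The day 35 knockout library held 72459160 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule), with a median of 3409 per barcode and a range of 500 to 87246. After filtering, 7886 cells with 48864984 UMIs and a median of 4616 UMIs and 2351 genes per cell were used.

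Znhit1, the targeted gene, was the first gene examined. It lies on the minus strand of chromosome 5 from 136982164 to 136988021 in mm10 and is annotated as protein coding (ENSMUSG00000059518). Germ-cell-like cells held 79 Znhit1 UMIs in 31980500, a level of 2.47 CPM (UMIs of a gene over all UMIs of the class, scaled to the usual unit; exact Poisson interval 1.96 to 3.08). Somatic-like cells held 234 in 15064246, a level of 15.5 CPM (13.6 to 17.7). The level was 6.29-fold lower in germ-cell-like cells (exact conditional binomial interval 4.85 to 8.22). It was 2.70 CPM in spermatogonium-like, 2.12 CPM in early-prophase-like and 2.60 CPM in pachytene-like cells. Among somatic-like classes of more than 20 cells, it ran from 10.7 CPM in macrophage-like to 19.95 CPM in interstitial stromal-like cells. A 3' tag can lie outside the deleted part of a gene, so UMIs that remained do not check the knockout label. A free-RNA estimate expected 54.7 UMIs in germ-cell-like cells against the 79 observed, with observed over expected at 1.45 (0.943 to 2.27). Its profile came from deposited barcodes of under 1000 UMIs, which held 31 Znhit1 UMIs and may include shallow cells. The estimate therefore does not settle how much was free RNA.

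**Figure D1:**
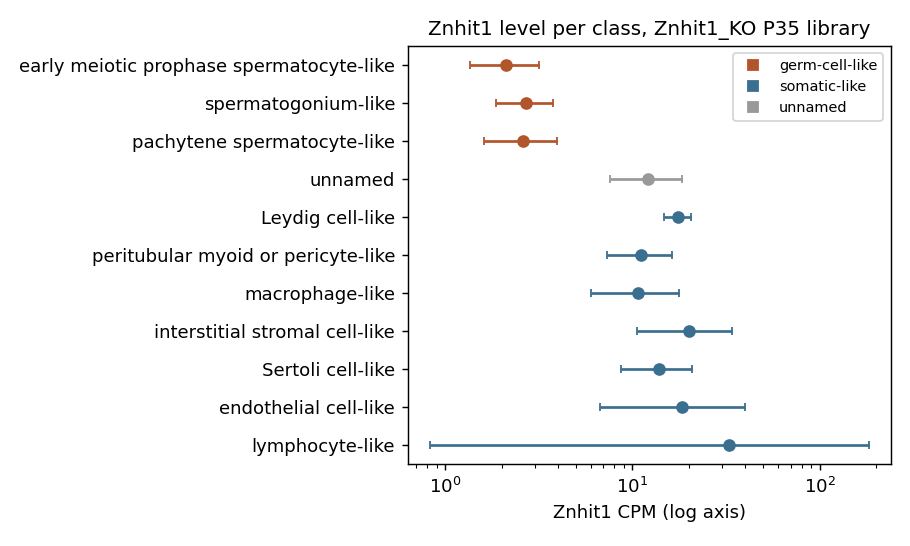
Znhit1 level of each class in the day 35 knockout library, as CPM on a log axis, with points for pooled UMIs of a class and bars for exact Poisson 95% intervals. The 3 germ-cell-like classes sit between 2.12 and 2.70 CPM, below the point of each somatic-like class.

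The other members of the list of H2A.Z and its deposition machinery lay differently. Of the 17 members, 15 had a higher CPM in germ-cell-like than in somatic-like cells and 12 were at least 2-fold higher. Znhit1 was the 1 member at or below a ratio of 0.5. No random lists were drawn for this comparison, so whether the list differs from other genes of like level was not tested. H2afz, which encodes H2A.Z.1, was at 1404 CPM in germ-cell-like and 672 CPM in somatic-like cells, a ratio of 2.09 (2.05 to 2.14). H2afv, which encodes H2A.Z.2, was at 658 and 319 CPM, a ratio of 2.06 (2.0 to 2.13). Srcap, the ATPase of the complex, had a ratio of 2.27 (2.07 to 2.49). H2afz lies on chromosome 3 from 137864487 to 137866922, and H2afv on chromosome 11 from 6427229 to 6444443.

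Cell classes were then described from markers fixed before the data were examined. Germ-cell-like cells made up 4268 of the 7886 cells (54.1%, Clopper-Pearson interval 53.01 to 55.23). They comprised 1570 spermatogonium-like cells (19.9%), 2170 cells like spermatocytes of early meiotic prophase (27.5%) and 528 pachytene-spermatocyte-like cells (6.70%, 6.15 to 7.27). Somatic-like cells numbered 2629 (33.3%), of which 966 were Leydig-cell-like, 675 like peritubular myoid cells or pericytes, 449 macrophage-like, 258 like interstitial stroma and 193 Sertoli-cell-like. A further 73 cells were endothelial-like and 15 lymphocyte-like. Clusters left without a name held 989 cells (12.5%), in 4 clusters with median UMI counts of 1250 to 1416, against 4616 over all cells used. The largest, of 645 cells, scored 1.34 for both Leydig and Sertoli markers, with Sertoli markers among its leading genes. Another, of 99 cells, scored highest for Sertoli markers (0.79). The others scored highest for spermatogonium (126 cells) and pachytene markers (119 cells). The counts of named classes leave all of these out and may be too low.

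No cluster was named late-spermatocyte-like, round-spermatid-like or elongating-spermatid-like. Of the 7886 cells, 0 lay in a spermatid-like cluster. For independently drawn cells, a limit of 3 counts is a share of 0.0380%, and the Clopper-Pearson upper bound was 0.0468%. Neither value limits the share of spermatids, since clustering can miss a small group. The smallest cluster found had 15 cells (0.190%). Single cells with RNA of spermatid markers are not bounded either. Of the 7886 cells, 31 (0.393%, 0.267 to 0.558) held 5 or more UMIs of the 17 spermatid markers. Over all 15306 barcodes, the protamine gene Prm1 had 10 UMIs and Prm2 had 7, and the transition protein genes Tnp1 and Tnp2 had 29 and 19. The acrosomal membrane gene Spaca1 held 827 of the 1457 UMIs of these markers and was at 30.6 CPM in pachytene-like cells. Pachytene-like cells also held 96 of 159 Izumo1 UMIs, 90 of 170 Gapdhs UMIs and 29 of 35 Smcp UMIs. Without Spaca1, 17 of the cells used held 5 or more UMIs of the other 16 markers. For Prm1, Prm2, Tnp1 and Tnp2 together, 0 cells did, with at most 2 UMIs in any. The classes of the 31 and 17 cells were not determined, so they may be pachytene-like cells.

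The pachytene-like class depended on a naming rule set after the clusters had been seen. Its 2 clusters held 371 and 157 cells. The first scored only slightly higher for pachytene than for early-prophase markers (2.14 against 2.01), and a rule asking for a lead of 0.25 left it unnamed. Under that rule the class held 157 cells, or 1.99% (1.69 to 2.32). In the second cluster, late-spermatocyte markers scored next highest, at 1.64 against 2.92 for pachytene markers. They also scored next highest in some spermatogonium-like and early-prophase-like clusters.

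**Figure D2:**
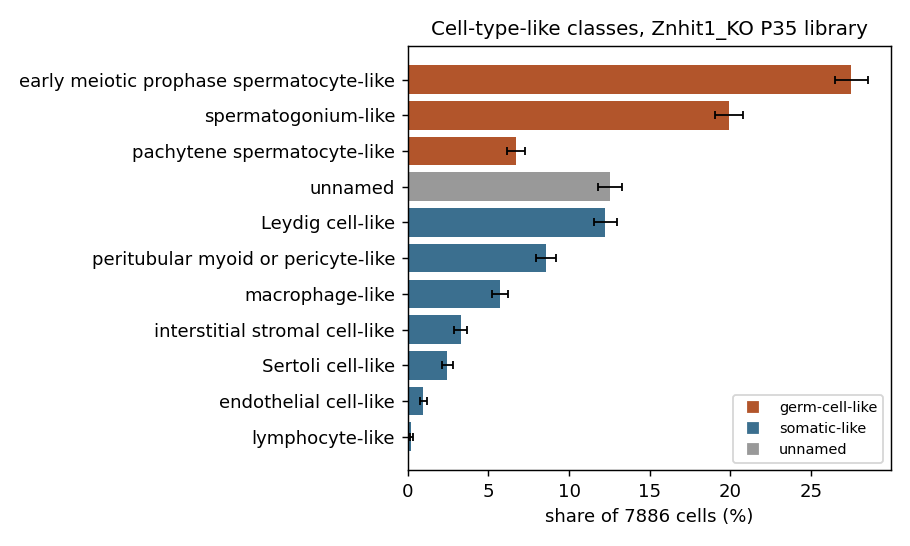
Share of the 7886 cells in each class of the day 35 knockout library, in percent, with bars for the share and whiskers for exact binomial 95% intervals. Early-prophase-like cells are the longest bar at 27.5%, and pachytene-like cells stand at 6.70%.

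X-linked and Y-linked RNA was lower in pachytene-like cells, the stage at which the sex chromosomes are known to be silenced in normal meiosis. X-linked genes gave 2.19% of UMIs in spermatogonium-like cells (2.18 to 2.20), 2.36% in early-prophase-like cells (2.35 to 2.37) and 0.691% in pachytene-like cells (0.685 to 0.696). The X-linked share was 3.42-fold lower in pachytene-like than in early-prophase-like cells (3.39 to 3.45), against a ratio of 1.08 (1.07 to 1.08) at the step before. The Y-linked share was 0.127% in early-prophase-like and 0.0265% in pachytene-like cells, 4.79-fold lower (4.58 to 5.01). With the rule that left the first pachytene-like cluster unnamed, the ratio of X-linked shares was 0.370, against 0.293, and it was 0.338 over the last early-prophase-like cluster only.

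Single genes followed the share. Of 571 X-linked genes with at least 20 UMIs over both classes, 447 were at least 2-fold lower in pachytene-like cells and 27 at least 2-fold higher. Among 14184 autosomal genes, 3717 (26.2%) were at least 2-fold lower and 2676 at least 2-fold higher. The median log2 ratio of the X-linked genes was -1.92, with a middle value of -0.32 for random autosomal lists matched on mean expression. It lay below all 10000 of these lists (percentile 0.0). All 10 measured Y-linked genes were at least 2-fold lower, with a median of -2.26. Taf7l, a germ-cell paralogue of a TFIID subunit and the X-linked gene of highest CPM, went from 673 to 115 CPM. Gm1993 and Spin2e were the X-linked genes with the largest upward ratios, from 0.0884 to 5.32 CPM and from 0.442 to 19.9 CPM. Gm15091 had the largest downward ratio, from 5.04 to 0.124 CPM. On the Y, Gm47283 went from 280 to 69.4 CPM and Gm3376 from 3.09 to 0.371 CPM. Several of these belong to families of near-identical copies, whose reads the counting could split, so their levels are uncertain.

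**Figure D3:**
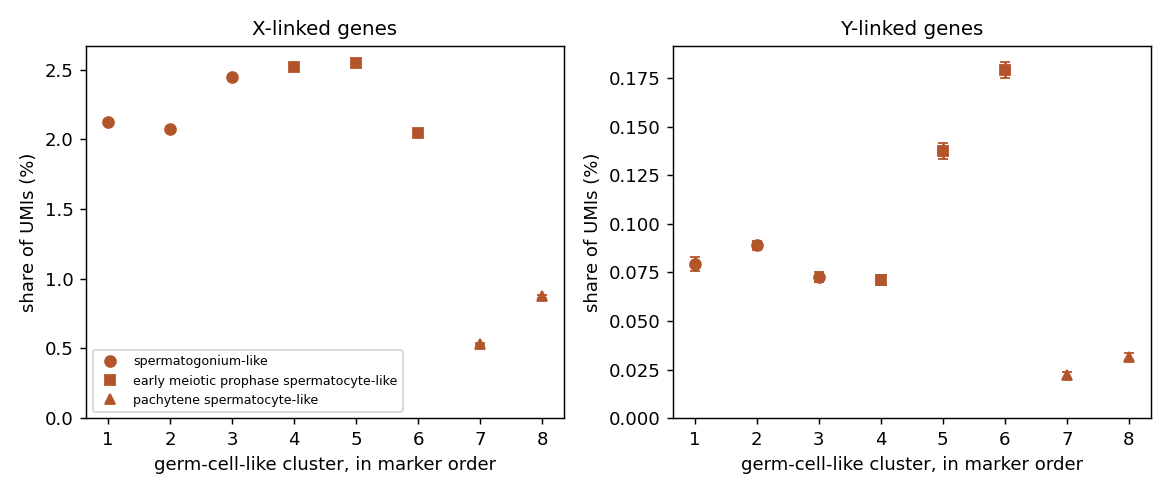
Share of UMIs from X-linked (left) and Y-linked (right) genes in the 8 germ-cell-like clusters, in percent, in an order set by markers, with exact binomial 95% intervals. The X-linked share lies between 2.04% and 2.55% in the first 6 clusters and at 0.533% and 0.873% in the pachytene-like clusters.

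Fixed gene lists were compared at the same step, from early-prophase-like to pachytene-like cells. Genes of these lists, and X-linked, Y-linked and mitochondrial genes, took no part in the clustering. The genes that did take part follow the same progression, so a list can still differ because the classes were told apart on its neighbours. The median log2 ratio over 14184 autosomal genes was -0.28. No result here says how a control testis would differ.

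Genes of later spermatogenesis were higher in pachytene-like cells. The axoneme and acrosome list had a median log2 ratio of 3.52 (95% order-statistic interval over members 1.49 to 4.30; above all random lists), and 19 of its 22 measured members were at least 2-fold higher. The median was 2.60 from the first pachytene-like cluster only, 2.91 with equal weight for each cell and 2.59 over the last early-prophase-like cluster only. Spag17, a protein of the axonemal central pair, went from 8.58 to 321 CPM, and Tekt4, a tektin of the axoneme, from 2.65 to 84.6 CPM. Meig1, needed for building the sperm tail, was the member of highest CPM, at 262 and 3178. Akap3, which encodes an anchoring protein of the fibrous sheath, was lower, at 2.65 and 1.11 CPM on 30 and 9 UMIs. The list of pachytene transcription and metabolism had a median of 1.85 (0.99 to 4.47; above all random lists), with 17 of 24 members at least 2-fold higher. Ldhc, the testis lactate dehydrogenase, went from 105 to 2737 CPM, a 26.0-fold difference (24.5 to 27.6) that depends on the cluster, with 768 CPM in the first pachytene-like cluster and 5017 CPM in the second. Pabpc2 went from 2.03 to 112 CPM. Gsg1 went from 0.177 to 17.2 CPM on 2 and 139 UMIs, a 97.3-fold ratio with an interval of 26.4 to 811. Taf4b, a gonadal TFIID subunit, was 9.65-fold lower (8.38 to 11.2).

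The piRNA pathway and germ granule list had a median of 0.98 (0.30 to 2.32; percentile 99.9), with 9 of 19 members at least 2-fold higher and 0 lower. Tdrd6, a tudor protein of the chromatoid body, went from 2.03 to 54.8 CPM and Tdrd1 from 24.6 to 231 CPM. Ddx4, the germ-cell helicase also known as Vasa, was at 353 and 699 CPM. Autosomal retrocopies of X-linked genes had a median of 1.87 (0.68 to 4.76; percentile 99.9), with 7 of 9 members at least 2-fold higher. Pgk2, the retrocopy of X-linked Pgk1, went from 0.707 to 25.6 CPM and Prps1l1 from 4.33 to 117 CPM. Utp14b was lower, at 48.2 and 22.7 CPM, and Rbmxl2 stood at 467 and 1062 CPM.

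Members of the recombination, cell cycle and synaptonemal complex lists went both ways, with list medians below 0. The meiotic recombination list had a median of -1.17 (-2.08 to -0.28; percentile 0.02), with 14 of 26 members at least 2-fold lower and 5 higher. Mei4, needed to form meiotic double-strand breaks, went from 45.0 to 0.990 CPM, 45.5-fold lower (22.9 to 106). Tex15 was 12.3-fold lower (11.2 to 13.4). Psmc3ip and Cntd1 went the other way, from 203 to 740 CPM and from 86.2 to 290 CPM. Cntd1 is known to act late, at crossover sites. The mitotic cell cycle list had a median of -1.36 (-2.13 to 0.51; percentile 0.02), with 10 of 18 members at least 2-fold lower and 2 higher. Mki67 was 7.47-fold lower (6.71 to 8.32) and Top2a 2.21-fold lower (2.12 to 2.30), whereas Mcm7 was 2.64-fold higher. Cdc20 was 2.33-fold higher, but went from 88.3 to 200 and 762 CPM within the early-prophase-like clusters and stood at 1033 and 587 CPM in the pachytene-like ones. The synaptonemal complex and meiotic cohesin list had a median of -0.54 (-1.61 to -0.04; percentile 1.03), with 7 of 21 members at least 2-fold lower and 2 higher. Its interval spanned 0 with equal weight for each cell (median -0.65, -1.65 to 0.25) and from the first pachytene-like cluster only (median -0.36, -1.52 to 0.11). Rad21l, a meiotic cohesin, was 11.8-fold lower (8.28 to 17.3), while Ccdc155, which encodes KASH5, was 2.99-fold higher. Sycp1 was at 3469 and 2886 CPM.

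The remaining lists lay within the central 95% of random lists. H2A.Z and its deposition machinery had a median of 0.39 (0.07 to 0.69; percentile 94.4), with 14 of 17 members within 2-fold. Ruvbl2 was 3.72-fold higher (3.38 to 4.10) and Ruvbl1 2.11-fold higher, whereas Anp32e, a chaperone that removes H2A.Z, was 3.69-fold lower (3.05 to 4.50). Most of the Anp32e difference lay within the early-prophase-like class, at 92.0, 58.1 and 21.2 CPM over its 3 clusters, against 14.1 and 17.6 CPM in the pachytene-like clusters. H2afz went from 1377 to 2479 CPM, a ratio of 1.80 (1.76 to 1.84), and H2afv from 562 to 606 CPM. Znhit1 had 24 and 21 UMIs in these classes, a ratio of 1.22 (0.649 to 2.30), so a difference was not detectable at this depth. The histone variant list had a median of 0.46 (percentile 85.3), with H2afy 6.14-fold and H3f3a 2.19-fold higher and H1fx 2.91-fold lower. The DNA damage response and sex body list had a median of -0.46 (percentile 11.8). In it H2afx was 1.81-fold higher (1.75 to 1.87) and Atm 12.5-fold lower (9.89 to 15.9). Most of the Atm difference lay within the early-prophase-like class, at 249, 65.2 and 15.2 CPM over its 3 clusters, against 10.4 and 8.28 CPM in the pachytene-like clusters. The p53 target and apoptosis list had a median of -0.24 (percentile 57.1), with Pmaip1 4.35-fold higher. The dissociation stress list had a median of -0.23 (percentile 48.5), with 0 of 14 members at least 2-fold higher and 3 at least 2-fold lower. Hspa1b was 3.17-fold lower (1.52 to 7.44), Dnajb1 was 1.99-fold higher (1.85 to 2.14), and Hsp90aa1 stood at 3776 and 7128 CPM.

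Many of these ratios depend on the clusters pooled in the early-prophase-like class. When pachytene-like cells were set against its last cluster only, a comparison chosen after the data had been seen, 26 of the 54 genes taken by the rule for named genes had a ratio more than 1.5 times away from the pooled one. The intervals of 3 list medians stayed above 0, at 2.59 (1.96 to 4.34) for axoneme and acrosome, 1.32 (0.35 to 3.71) for pachytene transcription and metabolism and 0.97 (0.36 to 4.33) for retrocopies. The other intervals all spanned 0. The meiotic recombination median was -0.34 (-0.71 to 0.30), the synaptonemal complex median -0.28 (-0.64 to 0.22), the mitotic cell cycle median -0.24 (-0.67 to 0.23), the piRNA pathway median 0.50 (-0.06 to 1.47) and the H2A.Z machinery median 0.35 (-0.32 to 0.61). The p53 target and apoptosis median changed sign to 0.21.

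For single genes over the same cluster, H2afv changed direction, from 838 CPM in the last cluster to 606 CPM, a ratio of 0.723 (0.692 to 0.756). Differences that kept their direction but shrank by more than 1.5 times included Rad21l at 5.20-fold lower (3.44 to 8.03), Mki67 at 4.84-fold (4.29 to 5.48), Taf4b at 3.43-fold (2.88 to 4.10), Tex15 at 2.32-fold (2.06 to 2.62), Atm at 1.61-fold (1.13 to 2.29) and Anp32e at 1.35-fold (1.01 to 1.79). Upward ones were Spag17 at 21.9-fold (16.9 to 28.9), Pgk2 at 20.3-fold, Tdrd6 at 13.6-fold, Meig1 at 6.13-fold, H2afy at 2.80-fold, Ruvbl2 at 2.44-fold, Cntd1 at 1.80-fold, Pmaip1 at 1.77-fold, Rbmxl2 at 1.40-fold, Hsp90aa1 at 1.26-fold and Cdc20 at 1.08-fold. H1fx had a ratio of 0.999 (0.932 to 1.07). Mei4, on 9 UMIs in the last cluster, had a ratio of 0.435 (0.146 to 1.27), and Gm15091, on 4 UMIs, of 0.122 (0.00249 to 1.24), both with intervals that span 1. The same held for Akap3, on 9 UMIs, at 0.490 (0.172 to 1.39) and Hspa1b, on 11 UMIs, at 0.401 (0.147 to 1.06). Gsg1 and Gm1993 had 0 UMIs in the last cluster, so their ratios there are lower limits. Ldhc was 19.4-fold higher (17.8 to 21.1). Gm1993 and Spin2e were at 0.231 CPM each in the first pachytene-like cluster and at 11.2 and 42.7 CPM in the second.

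**Figure D4:**
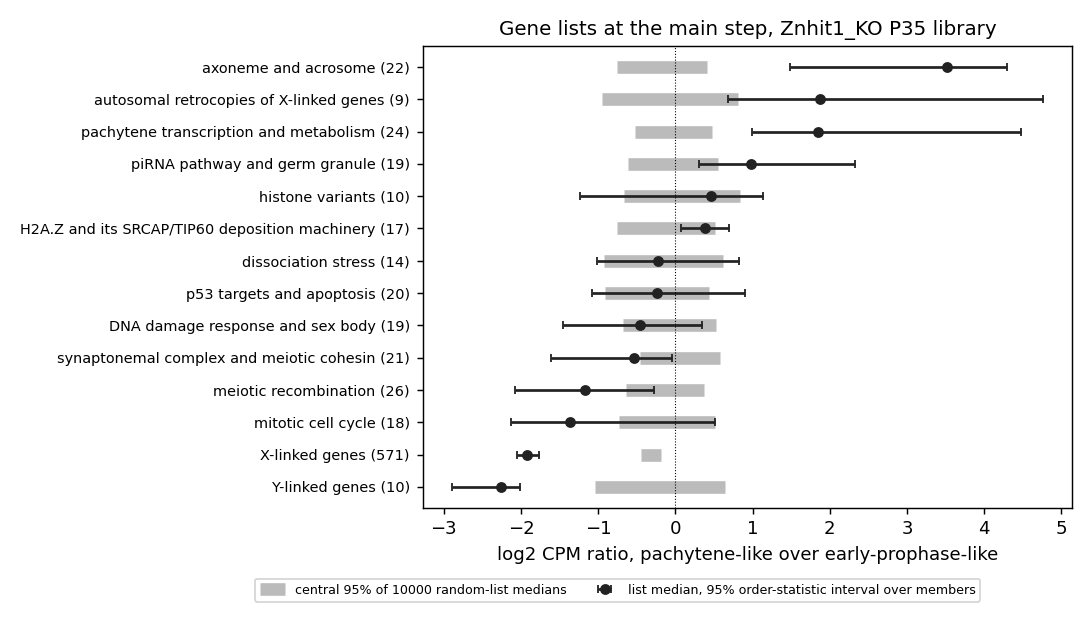
Median log2 CPM ratio of each gene list, pachytene-like over early-prophase-like cells, with 95% order-statistic intervals over members; grey bars hold the central 95% of medians of 10000 random lists, and measured members are in brackets. Axoneme and acrosome genes have the highest median at 3.52 and Y-linked genes the lowest at -2.26.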

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

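Alternatives that used 1 pachytene-like cluster, the last early-prophase-like cluster, the other naming rules or no haemoglobin-rich cells were chosen after seeing the data. No paired analysis was possible because each group had 1 library and no result came from a test. Of 210 alternative values for 17 results, 189 lay within the interval of the reported value and 21 outside it. The cause was not tested unless stated. The germ-cell-like share of 54.1% became 40.0% with a minimum of 200 genes and 500 UMIs, where Scrublet called 0 of 11154 cells and so did not work. It was 47.3% with up to 20% mitochondrial UMIs, 55.7% with 2000 variable genes, 49.4% with a lead also required between consecutive germ stages, and 55.7% without the rule on clusters of few UMIs, which named 1 of the 4 such clusters and left 863 cells unnamed. The pachytene-like share of 6.70% was above each of the 5 alternatives fixed beforehand, at 5.18% with the lower minimum, 4.97% with up to 20% mitochondrial UMIs, 5.59% with doublets kept, 5.72% at resolution 2 and 5.73% with 2000 variable genes. It was 1.99% with the required lead, by construction, since that rule leaves the first cluster unnamed. The spermatid-like share was 0 in all 7 alternatives. The ratio of germ-cell-like to somatic-like Znhit1 CPM, 0.159, ranged from 0.156 to 0.169. The ratio of X-linked shares at the main step, 0.293, was 0.309 with the lower minimum, 0.305 with up to 20% mitochondrial UMIs, 0.306 with doublets kept, 0.299 at resolution 2, 0.299 with 2000 variable genes and 0.307 with equal weight for each cell. It was 0.226 from the first pachytene-like cluster only, 0.370 from the second only, 0.370 with the required lead, and 0.338 over the last early-prophase-like cluster only. All 168 list medians lay within the main interval over members, but that interval shows the spread between members and is no measure of stability. The axoneme and acrosome median of 3.52 was 2.60 from the first pachytene-like cluster only, 3.97 from the second only and 2.91 with equal weight for each cell. The DNA damage response median of -0.46 was -0.14 from the first cluster only and -0.93 from the second only. Over the last early-prophase-like cluster only, the meiotic recombination median of -1.17 was -0.34 the mitotic cell cycle median of -1.36 was -0.24, the retrocopy median of 1.87 was 0.97, the axoneme and acrosome median was 2.59, the piRNA pathway median of 0.98 was 0.50, the synaptonemal complex median of -0.54 was -0.28, and the p53 target median of -0.24 changed sign to 0.21. The dissociation stress median also changed sign, from -0.23 to 0.33 with the lower minimum. Depth limits the genes of few counts, such as Znhit1 with 79 UMIs in germ-cell-like cells, or Gm1993 with 1 and 43 UMIs at the main step.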

Other observations

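The tests of the Znhit1 level and of the missing spermatids were chosen after the values had been seen. The tests of the X-linked share were written before their own values were seen, but after the X-linked share of each cluster had been. The bounds of both Znhit1 tests were rewritten after a first version had been run.

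Y-linked Zfy1 and Zfy2, zinc-finger genes known for a role at the meiotic checkpoint, had their highest level in the last early-prophase-like cluster. Zfy1 was at 13.6 CPM in the first early-prophase-like cluster, 170 CPM in the second and 446 CPM (425 to 467) in the third. It was at 18.2 CPM (14.4 to 22.7) in the first pachytene-like cluster and 39.3 CPM (33.2 to 46.1) in the second. Zfy2 went from 13.3 to 203 and 513 CPM (491 to 536) over the same 3 clusters and stood at 27.0 and 77.7 CPM in the first and second pachytene-like clusters. X-linked Scml2, a germ-cell Polycomb protein, was at 756 CPM in the third early-prophase-like cluster, 118 CPM in the first pachytene-like cluster and 186 CPM in the second.

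Within the pachytene-like class, the X-linked share was 0.533% (0.526 to 0.540) in the first cluster and 0.873% (0.864 to 0.883) in the second. Over 346 X-linked genes with enough UMIs, the median log2 ratio of the second to the first cluster was 0.21 (0.09 to 0.31), above all matched random lists. Of these, 85 were at least 2-fold higher and 31 at least 2-fold lower. Higher genes also outnumbered lower ones among 11539 autosomal genes, with 1838 at least 2-fold higher and 1185 at least 2-fold lower. Without the 10 X-linked genes of largest gain, a choice that by construction shrinks the difference, the shares were 0.499% and 0.604%. Slxl1 went from 19.14 to 1123 CPM, a 58.7-fold ratio (47.2 to 73.8), and Tsga8 from 44.1 to 663 CPM. Slxl1 belongs to a multicopy family, so its level is uncertain. Ldhc went from 768 to 5017 CPM between the same clusters. The second cluster had the higher median UMI count, 20128 against 10040, and the higher median doublet score, 0.0600 against 0.0318. It also stood later by markers, with a late-spermatocyte minus early-prophase score of 0.81 against -0.54. Stage, depth and doublets were not told apart.

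The first pattern weighed is the low Znhit1 level of germ-cell-like cells. Of 2360 autosomal genes within 1.5 times its mean CPM, 16.7% had a lower ratio of germ-cell-like to somatic-like CPM, so a difference of this size is not rare between these cell types, although the median log2 ratio of those genes was 0.03. Free RNA from broken cells could supply part of the 79 UMIs. With a profile from barcodes under 1000 UMIs and a free-RNA share of 14.4%, observed over expected was 1.45, with an interval of 0.943 to 2.27 that leaves it open whether free RNA supplied them all. Each of those barcodes held at least 500 UMIs, so the profile may include shallow cells and not free RNA alone. Loss of Znhit1 in the knockout stays open as an untested explanation, since no control counts were analysed here.

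The second pattern is the low X-linked share of pachytene-like cells. A few abundant autosomal genes taking the counts would lower all other genes alike, and the X-linked median log2 ratio of -1.92 lay below all matched autosomal lists (percentile 0.0). A few X-linked genes setting the share is argued against by 78.3% of 571 genes being at least 2-fold lower, against 26.2% of autosomal genes. Sex-chromosome silencing in these knockout cells is a hypothesis that would give both X-linked values. Whether its extent equals that of a control was not tested. Free RNA was not subtracted, and somatic-like cells had an X-linked share of 3.27%. The median UMI count was 4539 in early-prophase-like and 12165.5 in pachytene-like cells. How much of the difference in X-linked share came from free RNA or depth was not tested.

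The third pattern is the absence of a spermatid-like cluster. If the filters used here had removed spermatids, removed barcodes would carry their markers, and 0 of 7420 removed barcodes (0.0%) held 5 or more UMIs of 17 spermatid markers, against 31 of the 7886 cells used. A count of 5 is harder to reach in removed barcodes, whose median was 1068.5 UMIs against 4616. Markers were present there, with 384 UMIs of the 17 in 350 removed barcodes, at most 3 in any. Their level was 16.3 CPM (14.7 to 18.0) against 22.0 CPM (20.7 to 23.3) in cells used. Without Spaca1 it was 4.96 CPM against 10.5 CPM. Prm1, Prm2, Tnp1 and Tnp2 together had 17 UMIs in removed barcodes, at most 1 in any barcode, and 48 in cells used. Their levels were 0.720 CPM (0.420 to 1.15) and 0.982 CPM (0.724 to 1.30), which agree within counting error. Loss of a few shallow spermatids to the filters stays open. Cells under the 500 UMIs that every deposited barcode reached were not seen, and losses during dissociation or cell calling stay open. A block of meiosis in the knockout may also account for it and is untested without control counts.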
